A study of Homo sapiens with 2 samples.

How the data were processed

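Accessible chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 2 human tumour cell lines. Hs700T is a line from a pancreatic tumour and MCF-7 is a breast cancer line. Per the labels' protocols, 70000 cells were plated per sample, transfected with a plasmid for expression of V5-tagged ZNF414 (a C2H2 zinc finger protein), and harvested 48 hours later. Nuclei from 50000 cells were then transposed for 45 minutes at 37 °C. The set holds 1 sample per cell line. No untransfected or empty-vector sample is among the files used here, so the effect of ZNF414 expression was not analysed here.

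The deposited files are peak lists made with MACS2, per the labels. The submitters' processing notes name Trim Galore, FastQC, Bowtie2 2.3.2, SAMtools 1.3 and MACS2, and the genome build hg19. The MACS2 settings and the handling of duplicate reads are not given in the sources used here. Peak positions were taken as hg19 from these notes and reach base 249219307 of chromosome 1 in Hs700T. Each list was called on a single sample. For each peak the deposited fold is the enrichment at its summit over the local background, and the deposited −log10 p and −log10 q values give its significance against that background. The deposited score equals 10 times the −log10 q, truncated, in 100.0% of the peaks of each list. The smallest −log10 q was 1.30 in Hs700T and 1.31 in MCF-7, which corresponds to a q threshold of 0.05. Fold, p and q are the authors' own and were used to describe, rank and filter peaks within a list, to recover summit pileups, and in 1 test in the closing observations that sets folds of paired peaks side by side.

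The lists give no read totals. However, the authors' fold and −log10 p of a peak together fix the whole-number summit pileup (the number of extended tags stacked at the summit) and the local background, because fold = (pileup + 1) / (background + 1) and p is the Poisson probability of a higher pileup. This relation was solved for every peak. A whole number met the deposited p to within 5% of the distance to the next whole number for 47579 of 47579 peaks in Hs700T and 52237 of 52239 in MCF-7, and the 2 peaks left were not used for pileups. In a check on 20000 simulated peaks, 100.0% of pileups were recovered. Their fold and p were made with the same relation that was solved, so this checks the calculation and not the relation. Of simulated pileups that were not whole, 0.0% passed as whole. These were all drawn far from a whole number, so that share was fixed in advance and does not measure false matches. The lowest background in a list is its genome-wide background, shared by 10102 peaks in Hs700T and 13415 in MCF-7. It is proportional to the number of tags times their extension length and was used to put both libraries on one scale. Pileups carry counting error, and duplicate reads, if kept, would not be independent molecules.

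Peaks on chromosomes 1 to 22 and X were analysed, and 60 peaks in Hs700T and 38 in MCF-7 on other sequences were left out. Peaks that overlapped by at least 1 bp counted as shared. The overlap that position alone gives was taken from 100 random circular shifts of one list within each chromosome. Overlap counting was checked against bedtools 2.31.1 on simulated lists. Shared peaks that were each other's best overlap by pileup were paired, and the log2 ratio of pileups over genome-wide background, MCF-7 minus Hs700T, was taken over bins of 1 Mb. A bin median was used genome-wide where a bin held at least 5 pairs. Strong peaks are those with a pileup of at least 10 times the genome-wide background. Intervals on shares are Wilson 95% intervals, and intervals on ratios of shares are 95% intervals on the log scale. Both cover counting error only. With 1 sample per line there is no replicate check, and no p-value between the lines is given. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

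Before the data were examined it was set that the line-only peaks named are the 10 per line with the highest −log10 q. The alternatives set then for the comparisons that were run were a −log10 q of at least 5, every sequence in the file for the number of peaks, equal numbers of peaks, a reciprocal overlap of 50%, and the summit lying inside a peak of the other list. The pileup scale, the strong-peak class, the 1 Mb bins, the paired ratios and the split of chromosome 5 were chosen after seeing the data. The planned comparisons of promoters, gene lists, gene domains and motifs need an hg19 annotation or sequence, which was not used here, and peaks are therefore given by position (hg19, 1-based) without the genes, exons or introns they lie in. The planned peaks at the ZNF414 gene were replaced by the position and chromosome of the nuclear peak with the highest summit pileup. The chromosome of ZNF414 was taken from a RefSeq table for GRCh38, of which no coordinate was used.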

Results

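The data are 2 lists of accessible chromatin regions, from Hs700T pancreatic tumour cells and MCF-7 breast cancer cells, both expressing V5-tagged ZNF414 from a transfected plasmid. The lists give the regions called open in each line after transfection for overexpression of this zinc finger protein. On chromosomes 1 to 22 and X, Hs700T had 47579 peaks covering 15.3 Mb and MCF-7 had 52239 peaks covering 14.5 Mb. The median peak width was 217.0 bp in Hs700T and 196.0 bp in MCF-7. The median fold over local background, as given by the authors, was 4.82 in Hs700T and 5.17 in MCF-7. Read totals are not in the lists, and depth was read from the genome-wide background, which scales with tag number times extension length. This background, recovered from the deposited fold and p, was 2.02 tags in Hs700T and 1.32 in MCF-7, a ratio of 1.53. At that background the lowest pileup called a peak was 9 in Hs700T and 7 in MCF-7. There was 1 sample per line, so no difference below has a replicate check.

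The nuclear peak with the highest pileup lay at the same place in both lines, on chromosome 19, the chromosome that carries ZNF414. It spanned 8576358 to 8578232 in Hs700T and 8576360 to 8578232 in MCF-7 (hg19). The summit pileup was 3375 in Hs700T, 1668 times the genome-wide background, and 9189 in MCF-7, 6962 times the background. The log2 ratio between the lines was 2.06, with MCF-7 higher. The summits lay at different bases of the peak, 8578066 in Hs700T and 8576677 in MCF-7. This ratio therefore does not compare the same base in the 2 lines. In MCF-7 the pileup was 5.21 times that of the next highest nuclear peak, and in Hs700T it was 1.73 times. That next peak was the same in both lists, starting at 22020533 on chromosome 17, and in Hs700T it had the higher −log10 q of the pair (2619 against 2510.0). Around the chromosome 19 peak the pileups were far lower: 14 other peaks lay within 500 kb in Hs700T and 14 in MCF-7, with a median pileup of 8.65 and 9.09 times background. None of these neighbours exceeded 22.2 times background in Hs700T or 21.97 times in MCF-7. The position was not set against an hg19 gene annotation here, so the overlap with ZNF414 itself was not checked.

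**Figure D1:**
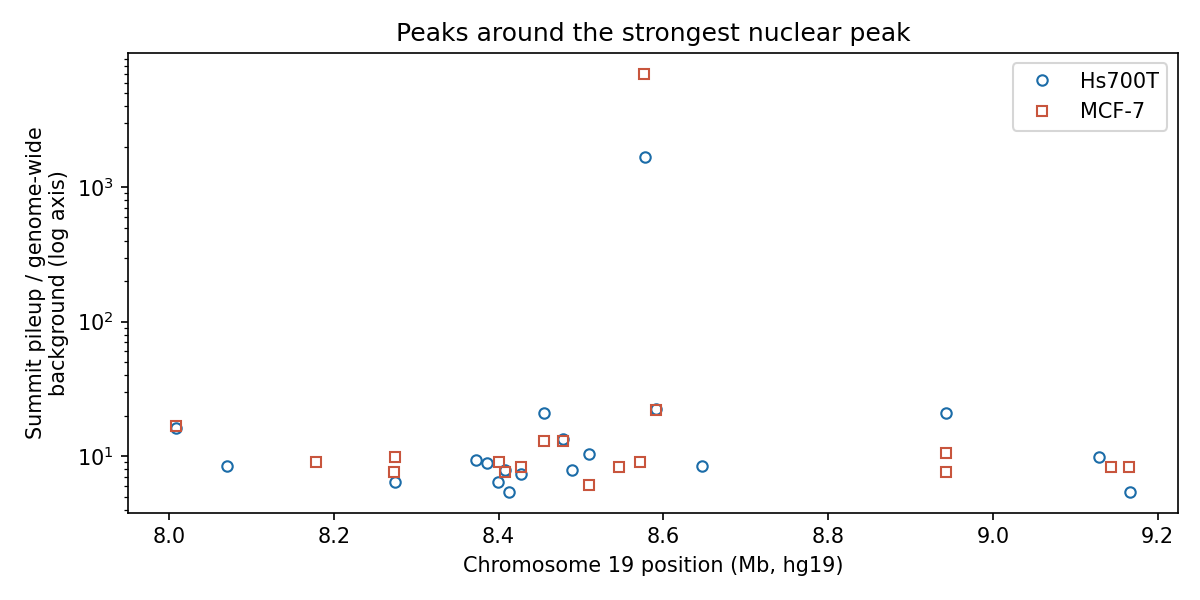
Summit pileup over genome-wide background (log axis) of each peak in the stretch of chromosome 19 (hg19) around the nuclear peak with the highest pileup, in Hs700T (circles) and MCF-7 (squares). The shared peak that starts at 8576358 in Hs700T reaches 1668 times background in Hs700T and 6962 times in MCF-7, while other peaks within 500 kb stay at or below 22.2 times.

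The next question was how much of the open chromatin the lines share. Of the Hs700T peaks, 25753 (54.1%, 95% interval 53.7 to 54.6) overlapped an MCF-7 peak, and of the MCF-7 peaks, 26436 (50.6%, 50.2 to 51.0) overlapped an Hs700T peak. After circular shifts of the other list the overlap averaged 1.06% for Hs700T and 0.981% for MCF-7, and the highest of the 100 shifts gave 1.22% and 1.62%. Shared peaks were the wide and strong ones. Their median width was 342.0 bp in Hs700T and 288.0 bp in MCF-7, against 148.0 bp and 149.0 bp for peaks found in one line only. The overlap rose from 12.7% in the weakest 10% of the Hs700T list to 95.1% in the strongest 10%, and from 16.98% to 89.3% in MCF-7. Among strong peaks, with a pileup of at least 10 times background, 4708 of 21440 in Hs700T (21.96%, 21.4 to 22.5) had no MCF-7 counterpart. In MCF-7, 10923 of 31122 strong peaks (35.1%, 34.6 to 35.6) had no Hs700T counterpart. These intervals do not overlap, but the class begins at a pileup of 21 in Hs700T and 14 in MCF-7. The overlap of all peaks depended on the rule: with a reciprocal overlap of 50%, 38.5% of Hs700T and 35.1% of MCF-7 peaks were shared.

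**Figure D2:**
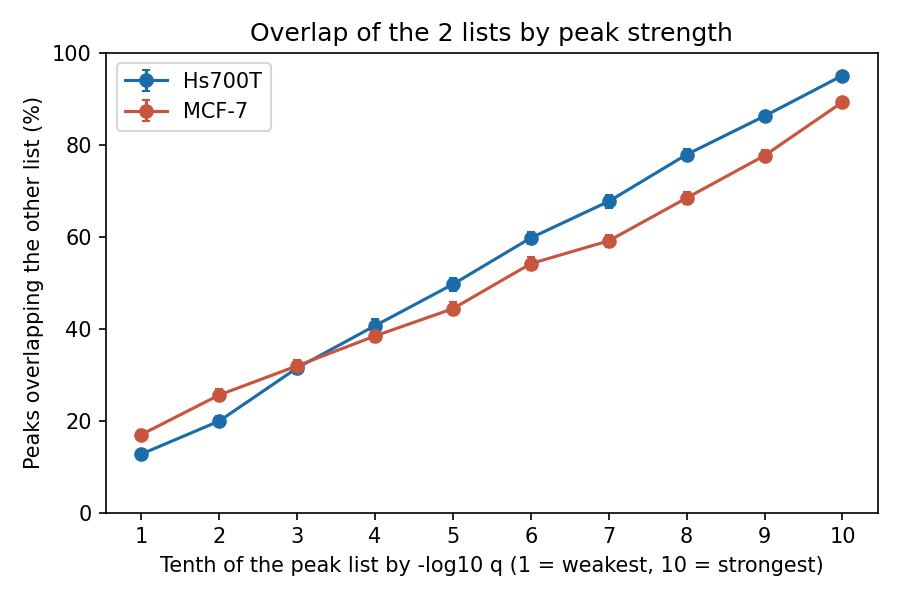
Percentage of peaks that overlap the other list by at least 1 bp, in 10 equal groups of each list ordered by the authors' −log10 q. Bars are Wilson 95% intervals, and the strongest group reaches 95.1% in Hs700T and 89.3% in MCF-7.

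The strongest line-only peaks of MCF-7 were concentrated on a few chromosomes. Of the 10 with the highest −log10 q, 4 lay on chromosome 17, 4 on chromosome 20, and 1 each on chromosomes 3 and 1. On chromosome 17 the peak at 57170805 to 57171541 had a −log10 q of 210.0 and a pileup of 285, and the peak at 59433827 to 59434529 a −log10 q of 209.9 and a pileup of 367. On chromosome 3 the peak at 64136454 to 64137041 had a pileup of 279. On chromosome 20 the peak at 49286944 to 49287512 had a pileup of 302, and the peak at 53072940 to 53073757 one of 227. Of the 100 strongest MCF-7-only peaks, 28 lay on chromosome 20, 22 on chromosome 17 and 18 on chromosome 3. Of the same 100, 46 lay in the 10 bins of 1 Mb with the largest MCF-7 excess of peaks. At the same fold a higher pileup gives a higher −log10 q, so a regional rise in tags alone can lift peaks in this ranking.

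The strongest line-only peaks of Hs700T were more spread out. The 10 with the highest −log10 q lay on chromosomes 1, 2, 5, 8, 10 and 18. Among them were the peaks at 248020323 to 248021240 of chromosome 1, with a pileup of 160, and at 109268 to 109544 of chromosome 18, with a pileup of 177. Chromosome 5 had 3 of the 10, at 3310744 to 3311649, 10507676 to 10508333 and 33008870 to 33009475, with pileups of 153, 155 and 121. Chromosome 8 had 2, at 49595151 to 49595868 and 134368475 to 134369346, with pileups of 132 and 175. In each line the line-only peak with the highest −log10 q was a narrow peak near the start of chromosome 1, at 565655 to 565742 in Hs700T (pileup 684) and at 567536 to 567628 in MCF-7 (pileup 712). Peaks were not screened here against regions prone to misaligned reads, so open chromatin at these narrow peaks is not shown. The same limit holds for every other peak named by position. Another narrow one among the Hs700T 10 was the 90 bp peak at 42392682 to 42392771 of chromosome 10.

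To compare the lines where both had a peak, 25354 shared peaks were paired. On the background scale the log2 ratio of pileups, MCF-7 minus Hs700T, had a median of 0.18 and an SD of 0.75 over pairs, so values below can be read against 0.18. The ratio moved in long blocks along the chromosomes. Of 1955 bins of 1 Mb with at least 5 pairs, 38 had a median more than 1 above the genome-wide median and 59 a median more than 1 below it. Counted from a ratio of 0 the order turned, with 65 bins above 1 and 23 below -1. The highest bin median was 4.45 (lowest and highest of its 6 pairs, 3.62 and 4.66), at 59 to 60 Mb of chromosome 17. Next came 46 to 47 Mb of chromosome 20, with 4.00 over 11 pairs, and 58 to 59 Mb of chromosome 17, with 3.56 over 10 pairs. Both 52 to 53 Mb of chromosome 20, with 32 pairs, and 64 to 65 Mb of chromosome 3, with 10 pairs, had a median of 3.21.

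**Figure D3:**
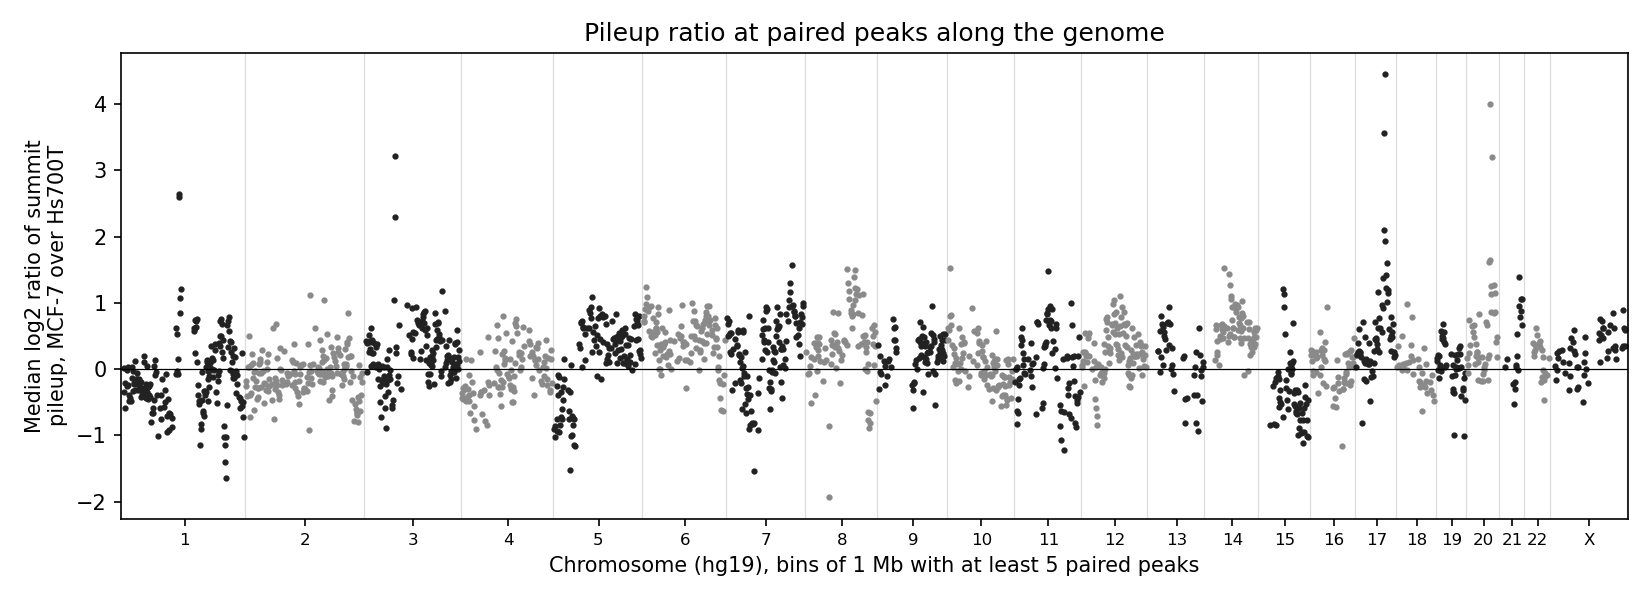
Median log2 ratio of summit pileup over genome-wide background, MCF-7 over Hs700T, in each 1 Mb bin with at least 5 paired peaks, along chromosomes 1 to 22 and X (hg19). Bins reach 4.45 on chromosome 17 and -1.94 on chromosome 8.

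Some stretches leaned to Hs700T. On chromosome 5, split after its bins had been seen, the median ratio was -0.71 (SD 0.76, 389 pairs) below 46 Mb and 0.45 (SD 0.56, 1109 pairs) from 50 Mb to the end. The lowest bin median was -1.94, at 48 to 49 Mb of chromosome 8, where the 15 pairs ran from -3.07 to 0.46.

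Peak numbers were also compared per bin. In the 10 bins with the largest MCF-7 excess there were 895 MCF-7 and 146 Hs700T peaks. Of these, 781 were MCF-7-only peaks with a recovered pileup. Their pileup and local background were divided by the factor by which the median pair ratio of their bin exceeded the genome-wide median. The background was kept at or above the genome-wide level. After this, 133 of the 781 still passed the weakest call of the MCF-7 list (−log10 p of 3.64). In the chromosome 1 bin the ratio rested on 3 pairs, from -0.76 to 2.67. Division removes weak peaks in any bin, and no other bins were treated alike. The count thus does not show why these peaks were called or what caused the regional rise. The bin at 59 to 60 Mb of chromosome 17 held 136 peaks in MCF-7 and 10 in Hs700T, and the bin at 52 to 53 Mb of chromosome 20 held 134 and 45. In these bins the local background was raised in MCF-7: the median over peaks was 11.4 times the genome-wide level at 59 to 60 Mb of chromosome 17 and 20.2 times at 52 to 53 Mb of chromosome 20, against 1.85 and 1.39 times in Hs700T. The longest run of consecutive MCF-7 peaks with no Hs700T peak starting among them had 74 peaks, over 1920 kb of chromosome 1 from 105680210 to 107600416. In the 10 bins with the largest Hs700T excess there were 560 Hs700T and 115 MCF-7 peaks. Of these bins, 6 lay on chromosome 5 and 3 on chromosome 8, with 1 on chromosome 7. The largest excess, at 12 to 13 Mb of chromosome 5, was 57 Hs700T against 3 MCF-7 peaks, with a median pair ratio of -0.23 over 3 pairs. The bin at 42 to 43 Mb of chromosome 5 held 69 Hs700T and 16 MCF-7 peaks, and the bin at 48 to 49 Mb of chromosome 8 held 71 and 23. Over these 10 bins the median pair ratio ran from -1.94 to 0.24. Pairs need a peak in both lists, so these ratios leave out the line-only peaks. The local background was higher in Hs700T than in MCF-7 in each of the 10 bins. Its median over peaks ran from 1.27 to 2.99 times the genome-wide level in Hs700T. In MCF-7 it was at most 1.24 times that level. The longest run of consecutive Hs700T peaks had 29 peaks, over 792 kb of chromosome 5 from 6963509 to 7755382.

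**Figure D4:**
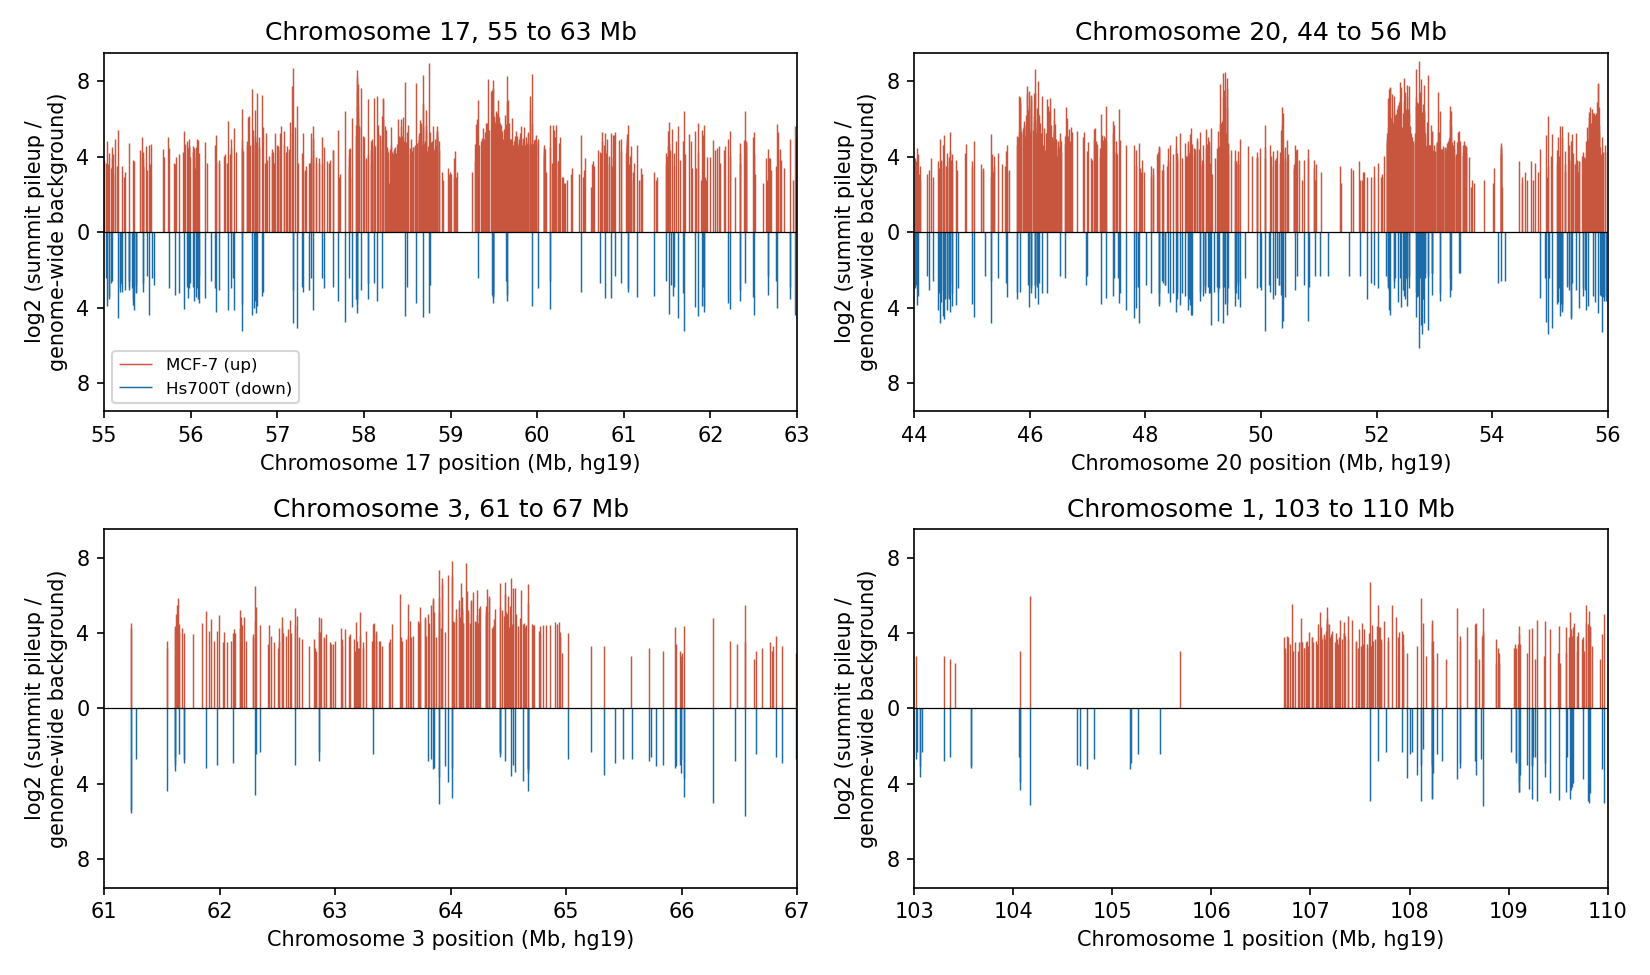
Log2 of summit pileup over genome-wide background of each peak in MCF-7 (upward) and Hs700T (downward) in 4 regions (hg19) with many MCF-7-only peaks. Dense blocks of MCF-7 peaks stand on chromosomes 17, 20 and 3, and the 74 consecutive MCF-7 peaks on chromosome 1 have no Hs700T peak starting among them.

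Whole chromosomes also took different shares of the lists. The share ratio, MCF-7 over Hs700T, was highest for chromosome 20 (1.55, 95% interval 1.43 to 1.67) and chromosome 17 (1.501, 1.40 to 1.605). Chromosomes 14 (1.44, 1.35 to 1.53), X (1.43, 1.32 to 1.56) and 6 (1.40, 1.33 to 1.478) followed. It was lowest for chromosome 15 (0.671, 0.630 to 0.715), chromosome 2 (0.753, 0.723 to 0.783) and chromosome 1 (0.771, 0.743 to 0.801). The interval excluded 1 for 18 of the 23 chromosomes. The median pair ratio was 0.46 for chromosome 20, 0.48 for 17, 0.62 for 14, 0.28 for X and 0.44 for 6. It was -0.38 for chromosome 15, -0.1 for 2 and -0.12 for 1, against 0.18 genome-wide. DNA copy number can differ between tumour lines and move peak calling. It was not measured, so the shares do not show chromatin differences by themselves. Without the 20 bins of largest excess the share ratio was 1.39 for chromosome 20 and 1.29 for chromosome 17. Both then ranked below chromosomes 14 (1.44), X (1.44) and 6 (1.41). With a −log10 q of at least 5, chromosome 14 (1.45) ranked above chromosome 17 (1.41). Chromosome 19, which holds the nuclear peak with the highest pileup, had a share ratio of 0.998 (0.924 to 1.08).

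**Figure D5:**
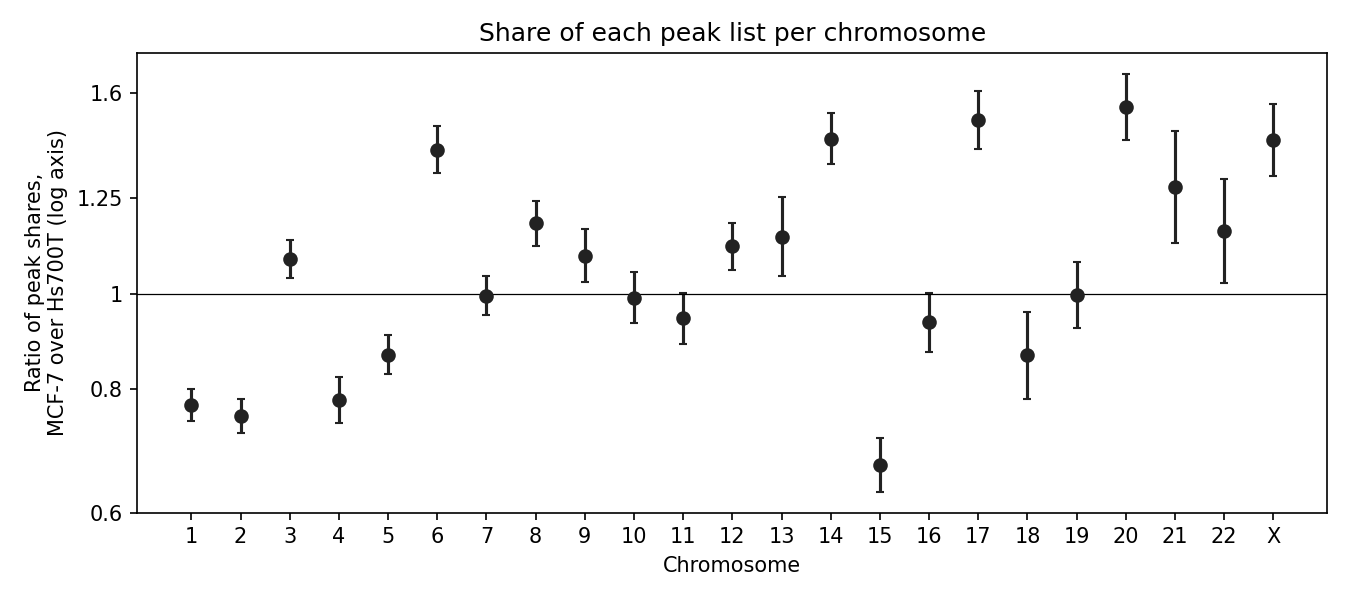
Ratio of the share of each peak list on a chromosome, MCF-7 over Hs700T (log axis), with 95% counting intervals as bars. Chromosomes 20 and 17 are highest at 1.55 and 1.501, and chromosome 15 is lowest at 0.671.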

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

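The mitochondrial genome was outside the comparisons, and it carried called peaks in both libraries. Hs700T had 12 peaks there, covering 9994 bp, and MCF-7 had 10, covering 10923 bp. The authors' fold ran from 1.24 to 3.55 in Hs700T and from 1.24 to 3.79 in MCF-7, and the highest −log10 q was 3332 in Hs700T and 5015 in MCF-7. Because fold is taken over the local background, these low folds do not show a low signal against the nuclear genome. No sample lacks these peaks and no biological explanation was tested.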

How the results depend on the processing

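With 1 sample per line no replicate could be left out, and with no replicates in the labels no paired analysis was possible because each line has a single sample. A −log10 q of at least 5 left 29246 peaks in Hs700T and 31088 in MCF-7, and every sequence in the file gave 47639 and 52277. The overlap, 54.1% of Hs700T and 50.6% of MCF-7 peaks, was 60.3% and 57.5% with a −log10 q of at least 5 and 52.9% and 53.9% with equal numbers of peaks, which turned the order of the lines. It was 38.5% and 35.1% with a reciprocal overlap of 50%, and 50.2% and 47.2% with the summit inside a peak of the other list. Alternatives chosen after seeing the data gave 54.5% and 51.2% outside the 20 bins of largest excess, and 78.0% and 64.9% for strong peaks. With the median pair ratio set to 0, strong MCF-7-only peaks numbered 9294 (33.0%) in place of 10923, against 4708 in Hs700T. Among chromosomes whose share ratio had an interval that excluded 1, the ratio changed sides with a −log10 q of at least 5 for chromosome 5 (1.04, from 0.868) and chromosome 22 (0.985, from 1.16). None of them changed sides with equal numbers of peaks or outside the bins. Measured by local background, the bin at 51 to 52 Mb of chromosome 8 had a ratio of -0.33 in place of 0.24. The cause was not tested for these changes. Of the 10 bins of largest excess per line, 9 stayed among the 10 for each line with equal numbers of peaks. Comparisons of promoters, gene lists, gene domains and motifs were not run, for want of an hg19 annotation and sequence. Depth limits weak peaks: at background, 9 tags were needed in Hs700T and 7 in MCF-7, so a peak missing from one list is not shown to be closed chromatin.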

Other observations

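The tests in this part were chosen after the results were seen. In the 488 bins of 1 Mb with at least 10 pairs and a median ratio within 0.25 of the genome-wide median, 2446 of 8800 strong MCF-7 peaks (27.8%, 95% interval 26.9 to 28.7) and 1015 of 6186 strong Hs700T peaks (16.4%, 15.5 to 17.4) were found in one line only. With the median pair ratio set to 0, the MCF-7 number was 2056 of 8006 (25.7%). The strong class still begins at fewer tags in MCF-7 (15) than in Hs700T (21). Some of these bins adjoin bins of uneven ratio. The bin at 85 to 86 Mb of chromosome 16 held 28 strong MCF-7-only and 6 strong Hs700T-only peaks around a median pair ratio of 0.18. The bin at 96 to 97 Mb of chromosome 7 held 8 strong Hs700T-only and 2 strong MCF-7-only peaks, and that at 195 to 196 Mb of chromosome 3 held 7 and 2.

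Over 23759 pairs in bins with enough pairs, the SD of the log2 ratio was 0.75 overall and 0.56 around the bin medians, or 0.47 when estimated from the median absolute deviation. Counting error alone gives an SD of 0.45. For the 1125 pairs with a pileup of at least 50 in both libraries, the values were 0.64, 0.42 and 0.36, with 0.24 from counting error. Of all pairs, 1838 (7.74%) lay more than 1 log2 unit from their bin median, and of those with a pileup of at least 50, 34 (3.02%) did. Counting error is part of this spread, and with 1 sample per line the rest cannot be divided between samples and lines.

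In the 10 bins of largest MCF-7 excess, on chromosomes 1, 3, 17 and 20, the paired peaks had a median log2 pileup ratio of 3.06, and 94.6% of the 112 pairs lay more than 1 log2 unit above the genome-wide median, against 7.24% elsewhere. A greater depth of the MCF-7 library is argued against by its genome-wide background, which was 0.652 times that of Hs700T. This holds if tags were extended alike in both libraries, which the sources used here do not give. More DNA copies of these segments in MCF-7, a line known for amplified segments on chromosomes 17 and 20, may account for the pattern, but the bins were picked for their excess and any regional rise would give a high share of pairs, so this share does not decide. More open chromatin on the same number of copies stays open too. The authors' fold at the pairs had a log2 ratio 0.19 above the genome-wide median, but the local background holds the peak's own tags, so this value decides nothing.

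The nuclear peak with the highest summit pileup lay on chromosome 19, the chromosome of ZNF414, in 2 of 2 lists. More DNA copies of the surrounding segment are argued against, since other peaks within 500 kb had a median pileup of at most 0.519% of the peak's own. Fragments of the transfected plasmid aligned to the ZNF414 gene may account for the peak, but its chromosome prompted this idea and is no test of it. A repeat collapsed in the reference, with the same copies in both lines, stays open. The log2 ratio of the peak, from summits at different bases, was 2.06, and other paired peaks whose edges agreed within 2 bp reached 2.09. Those with a fold over 15 in Hs700T had a median of 1.03. They were 91 to 472 bp wide, while the chromosome 19 peak had a fold of 14.0 and a width of 1875 bp in Hs700T. These equal-edge peaks were not shown to be repeats, so the ratio of 2.06 decides nothing. Open chromatin at the gene itself was not tested.

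Of 25354 pairs, 119 (0.469%) had both edges within 2 bp of each other in the lines. Of these, 19 had a fold over 15 in Hs700T, with widths of 91 to 472 bp and log2 ratios from 0.22 to 2.09.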
